A study of Mus musculus with 2 samples.

How the data were processed

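Cells labelled as GL261, a mouse glioma cell line, were cultured in DMEM with serum, and their total RNA was extracted with Trizol and made into sequencing libraries with a SMARTER mRNA kit, per the labels' protocols. The series holds 2 libraries: 1 is labelled WT and 1 PTEN knockout. Each deposited file gives a raw read count per gene name, as the whole numbers and the different totals of the 2 files show; no scaling by the authors is visible in them. The genome build was GRCm38 (mm10), per the submitters' processing notes. The aligner, the counting tool, the annotation release, the strand setting and the editing method are not given in the sources used here. Both files list the same 54429 gene names, with Pten in the first row.

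Gene names were matched to GENCODE M21, an annotation of the same build, and 53840 of them (98.9%) were found. Of the names found, 112 stand for more than 1 gene of that annotation, among them Aldoa and Ddit3, and received no position, GC content or length. In 11 names a spreadsheet-style date replaces a symbol; these hold 8937 counts in the WT and 8576 in the knockout library and are not named in the text. Because strand use is not stated, reads of overlapping sense and antisense genes cannot be separated, and reads of near-identical gene copies can be shared between them.

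Counts were scaled with edgeR 4.0.16 TMM factors (0.990 for WT and 1.01 for the knockout), and CPM values use these effective totals. With 1 library per group there are no residual degrees of freedom, so no test across genes was run and no p-value is given. Each ratio compares these libraries, not the genotypes. Ratios are knockout over WT, with an exact 95% interval from the binomial distribution of the knockout share of a gene's summed count (Clopper-Pearson); single values carry exact 95% Poisson intervals. These intervals cover counting error only. PCR duplicates and differences between cultures come on top and were not measured. Where a gene is called lower by some fold, the value is the inverse ratio, WT over knockout, with its interval. A gene with 0 counts in a library was set at a floor of 3 counts there, and its fold is written as "at least" against that floor. The floor leaves out the counting error of the other library and lies under the upper end of the exact 95% Poisson interval of a 0 count (0.241 CPM in WT for Muc5ac, 0.239 CPM in the knockout for Rgl3). The bound of the exact interval of the ratio, which is smaller, is therefore given beside each such fold.

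A gene was measured when its summed count was at least 20. It was called higher or lower when its ratio was at least 2-fold and the interval excluded 1. Before the data were examined, 35 gene lists were fixed, with the rule for named genes. The named genes are Pten and the 14 highest and 14 lowest, ranked by the interval bound nearest to 1. Names of the Gm, Rik, pseudogene, microRNA, snoRNA or bare-identifier kind were left out of that ranking. From each list come up to 3 higher and 3 lower members, or the 2 most abundant where none passed. For lists of other cell types and of RNA quality the 4 most abundant members are named. A list's median log2 ratio was placed among 10000 random lists of the same size, drawn from measured genes outside the list with the same names left out and matched on expression in 20 bins, where at least 3 members were measured. The 95% order-statistic interval of each list median is taken from the ranked ratios of its members and treats them as independent. Members of a pathway vary together, so these intervals can be too narrow. For the same reason the percentiles describe the 2 libraries and are not p-values.

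The steps were tested on simulated Poisson counts for the knockout against WT comparison (14045 genes measured). Of 50 genes simulated at 2.5-fold, 49 were called in the right direction, as were all 50 at 4-fold and all 50 at 8-fold; of 50 at 1.5-fold, 1 passed the 2-fold rule. Of 13846 unchanged genes 67 were called, and 10 of 200 unchanged lists fell outside the central 95% of random lists. Those lists were drawn at random from the same simulated genes, so about that share falls outside by construction. Lists of genes that vary together were not simulated. The simulation holds no variation between cultures. Alternatives were scaling by total count, by DESeq2 1.42.0 size factors or by upper quartile, a pseudocount of 5, thinning of the deeper library and other minimum counts (1 and 100), and leaving out Gm, Rik and similar names. Fold thresholds of 4 and 1.5, a stricter or no interval rule, another background for random lists and removal of a loess trend (span 0.3) on GC content and exon length completed them. Intervals and random lists were computed with scipy 1.17.1 and numpy 2.4.6.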

Results

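The comparison asked how depletion of PTEN bears on gene expression. It set the transcriptome of cells labelled as GL261, a mouse glioma line, against that of cells labelled as GL261 knocked out for PTEN. In both libraries epithelial keratin transcripts were abundant (Krt8 had 21952 and 24549 counts), and 20 of 32 glial and neural genes had fewer than 20 summed counts; the identity of the cells rests on the labels alone. Pten encodes the lipid phosphatase that opposes PI3K and so restrains AKT and mTOR signalling. The WT library held 15435592 counts and the knockout library 15258912, and on the TMM-scaled totals the floor of 3 counts corresponds to 0.196 CPM in WT and 0.195 CPM in the knockout. The WT library had at least 1 count for 21271 gene names and the knockout library for 22658. Mitochondrially encoded genes took 2.18% of counts in both, and the 10 most abundant genes took 4.66% in WT and 4.54% in the knockout. There was 1 library per genotype, so no difference reported here has a replicate check.

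The Pten transcript was lower, but abundant, in the knockout library. Pten (ENSMUSG00000013663.7; GRCm38 chromosome 19, positions 32757497 to 32826160, plus strand) had 4799 counts in WT and 3152 in the knockout. Its level was 314 CPM (95% interval 305 to 323) in WT and 205 CPM (197 to 212) in the knockout, which is 1.54-fold lower (95% counting interval 1.47 to 1.61). The counts sum over the whole gene and the site of the edit is not in the labels. A frameshift can leave a transcript in place, so this value does not measure loss of the protein.

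Of 14002 measured genes, 925 were at least 2-fold higher and 624 at least 2-fold lower in the knockout library, together 11.1%. Many were weakly expressed: the median summed count was 60 for the higher and 94 for the lower genes. With a summed count of at least 100, 342 were higher and 301 lower. At 4-fold or more, 287 genes were higher and 117 lower. The log2 ratios of measured genes ran from -0.98 at the 5th percentile to 1.26 at the 95th, around a median of -0.03.

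**Figure D1:**
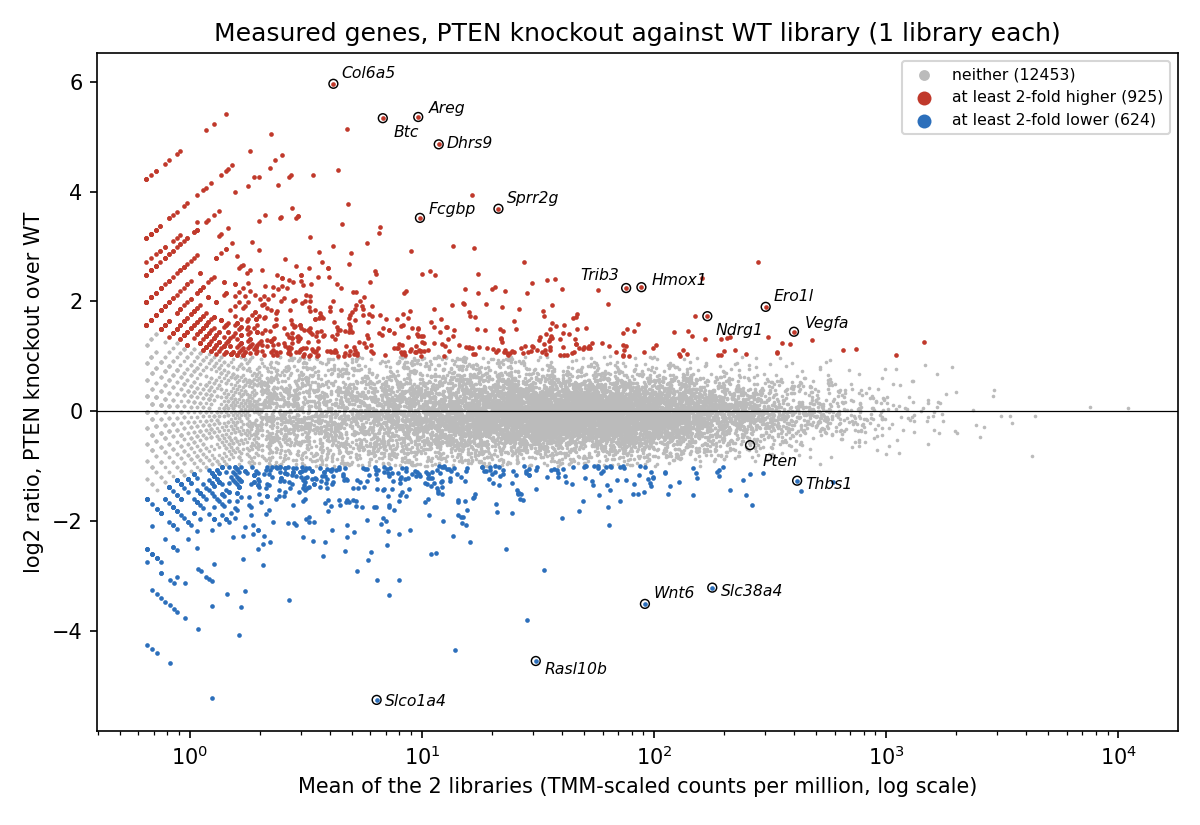
Log2 ratio of the knockout over the WT library against the mean level in TMM-scaled CPM (log axis), 1 point per measured gene; genes at 0 in a library are drawn with the floor of 3 counts there. The 925 higher and 624 lower genes lie mostly at low levels, and Pten sits at -0.62.

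The genes with the highest ratios mostly had few or no counts in WT. Areg and Btc, which encode the EGFR ligands amphiregulin and betacellulin and lie near each other on chromosome 5 (from 91139599 and 91357261), were 41.1-fold (19.7 to 103) and 40.5-fold (17.1 to 126) higher. Areg went from 7 to 290 counts and Btc from 5 to 204. Muc5ac, a secreted gel-forming mucin, had 0 counts in WT and 77 in the knockout, at least 25.4-fold higher against the floor of 3 counts (interval bound 20.2). Hnf4a, a transcription factor of liver and gut epithelium, went from 0 to 58 counts and was at least 19.2-fold higher against the floor (interval bound 15.1). Against the same floor Epha4, an ephrin receptor, was at least 15.9-fold higher (interval bound 12.4) and the lincRNA Tslrn1 at least 23.8-fold (18.9). Col6a5, a collagen VI chain, had 2 counts against 126 (ratio 62.5, 16.9 to 521), and the fibrinogen chain gene Fgb 2 against 67 (ratio 33.2, 8.84 to 279.9). Dhrs9, a retinol dehydrogenase family gene, was 29.1-fold higher, the transcription factor gene Lmx1a 35.2-fold, and the potassium channel subunit gene Kcne3 19.8-fold. Among genes with more WT counts, the adaptor gene Blnk went from 31 to 477 (15.3-fold, 10.6 to 22.7). Sprr2g, annotated in GENCODE M21 as a polymorphic pseudogene, went from 47 to 611 (12.9-fold). It belongs to a multigene family of epithelial envelope proteins whose reads can be shared. Fcgbp, a mucus-associated protein gene, went from 24 to 278 (11.5-fold).

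The genes with the lowest ratios included several that were well expressed in WT. Slc38a4, an amino acid transporter, went from 4917 counts to 534 and was 9.29-fold lower (8.49 to 10.2). Wnt6, a secreted Wnt ligand (chromosome 1, 74771892 to 74785322), went from 2567 to 227 counts, 11.4-fold lower (9.96 to 13.1). Notum, a secreted enzyme that inactivates Wnt proteins, was 7.47-fold lower (6.18 to 9.11). Rasl10b, a small GTPase gene, was 23.5-fold lower (17.03 to 33.2), with 907 counts against 39. Cfh, complement factor H, was 14.1-fold lower, Gabrp, a GABA receptor subunit, 20.4-fold, and Slco1a4, an organic anion transporter, 38.3-fold. Tnfrsf11b, which encodes osteoprotegerin, was 8.46-fold lower. The clock-related gene Npas2 had 37 counts in WT and 1 in the knockout (WT over knockout ratio 37.3, 6.30 to 1513). With 0 counts in the knockout and against the floor of 3, Rgl3 was at least 16.8-fold lower (interval bound 13.2), Eddm3b at least 8.74-fold (6.62) and Ctnna2 at least 8.41-fold (6.34). Apoc1 and Xlr were at least 7.73-fold lower (5.80 for both); Xlr belongs to a family of similar copies.

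**Figure D2:**
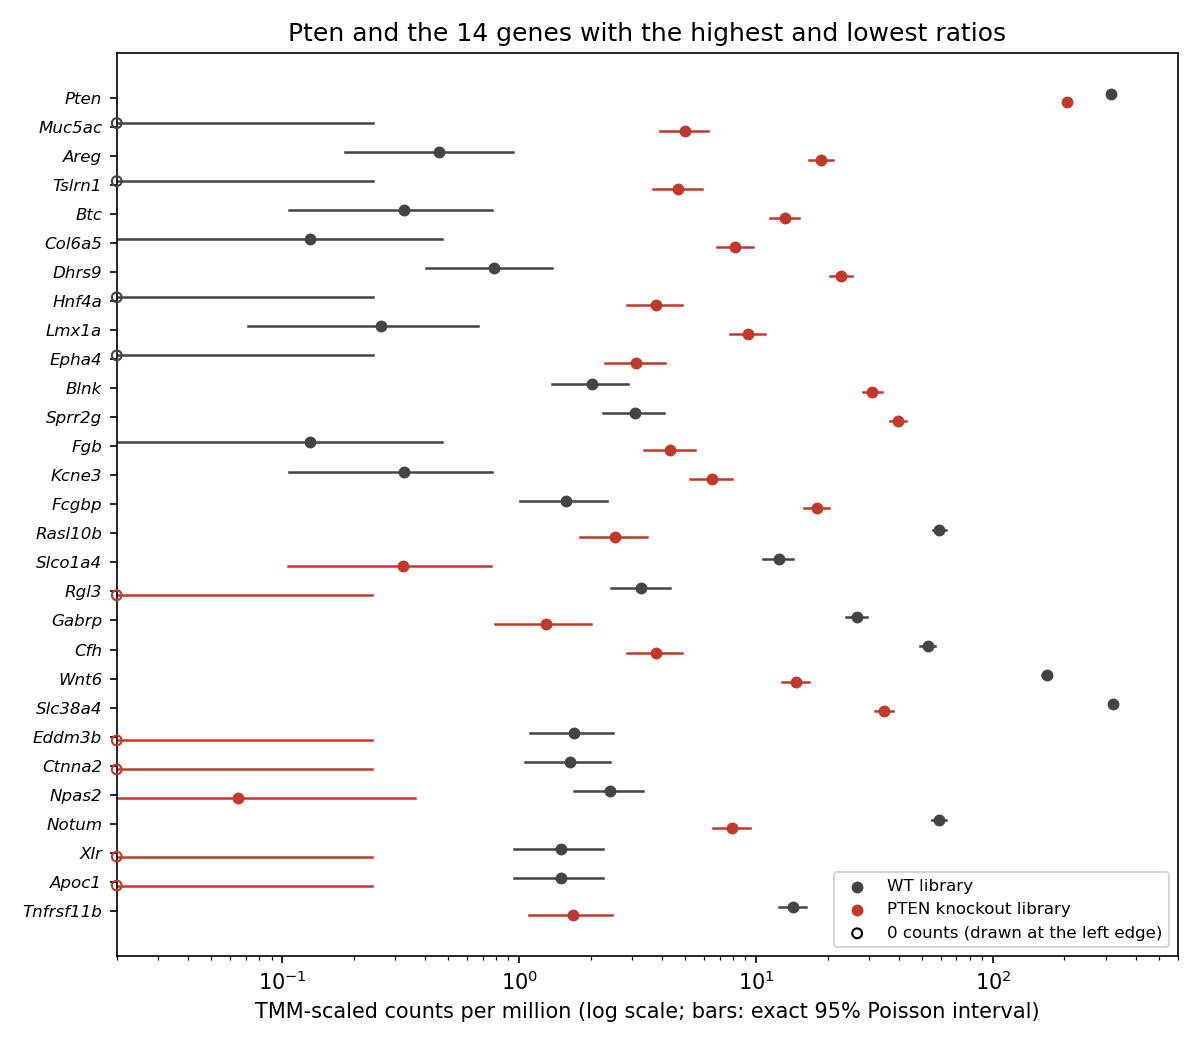
Level in TMM-scaled CPM (log axis) of Pten and of the 14 genes with the highest and the 14 with the lowest ratios, in the WT (grey) and knockout (red) library; bars are exact 95% Poisson intervals and open symbols mark 0 counts. Pten differs 1.54-fold, from 314 to 205 CPM, which is less than any other gene shown.

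Because PTEN acts on PI3K, components and outputs of that pathway were examined first. Of 29 measured PI3K-AKT-mTOR components, 3 were higher, 1 was lower and 25 were neither. Pik3r3, a regulatory subunit, was 3.88-fold higher (3.16 to 4.79), and the phosphatase genes Inpp5d and Inpp4b were 3.57-fold and 3.51-fold higher from 15 and 13 WT counts. Pik3r1, the main p85 regulatory subunit, was 2.03-fold lower (1.81 to 2.27), and under 2-fold with total count scaling (log2 ratio -0.99), upper quartile scaling (-0.96) or the GC and length trend removed (-0.97). The list median was -0.08 while its mean, of opposite sign, was 0.06, and the median lay at the 33.7th percentile of random lists. Of 23 genes activated by FOXO factors, which AKT inhibits, Gadd45a was 2.16-fold higher and Foxo4 2.09-fold lower (log2 ratio -1.06, or -0.96 with the trend removed); the median of -0.05 lay at the 49.6th percentile.

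Genes of the ATF4 response, HIF targets and glycolysis genes were higher as groups in the knockout library. In the ATF4 and amino acid response list, 9 of 29 genes were higher, none was lower and 24 had ratios above 1. The median log2 ratio was 0.61, which none of the 10000 random lists exceeded. Trib3, Chac1 and Ddit3, all targets of the stress factor ATF4, were 4.74-fold (4.25 to 5.29), 4.68-fold (3.80 to 5.82) and 4.44-fold (3.74 to 5.31) higher. Of 17 HIF targets 4 were higher and none lower, with a median of 0.56, likewise above the random lists. Ero1l, an endoplasmic reticulum oxidase, was 3.73-fold higher (3.55 to 3.93), Ndrg1 3.32-fold (3.11 to 3.54) and the angiogenic factor Vegfa 2.73-fold (2.62 to 2.84). No glycolysis gene reached 2-fold, but 15 of 18 had ratios above 1 (median 0.31, 99.9th percentile); Pkm was at 1.21-fold and Aldoa at 1.27-fold. None of 20 chaperone and unfolded protein response genes reached 2-fold (median 0.20, 99.5th percentile, order-statistic interval -0.07 to 0.46), with Hspa5, the main lumenal chaperone, at 1.71-fold and Hsp90b1 at 1.33-fold. Of 21 NRF2 targets 3 were higher and none lower (median 0.17, 98.95th percentile, order-statistic interval -0.14 to 0.61): the haem oxygenase gene Hmox1 (4.79-fold, 4.33 to 5.30), the cystine transporter gene Slc7a11 (2.67-fold) and the ferritin gene Ftl1 (2.03-fold). Slc7a11 is also among the 9 higher genes of the ATF4 list. Medium state and cell density at harvest are not given in the sources used here.

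By their list medians, targets of p53 were higher and S phase genes lower as groups. Of 24 measured p53 targets 5 were higher and none lower, 22 had ratios above 1, and the median was 0.55, above the random lists. Pmaip1, a BH3-only death gene, was 2.47-fold higher (2.33 to 2.63), Ccng1 2.12-fold (2.04 to 2.21) and the cell cycle inhibitor gene Cdkn1a 2.10-fold (2.01 to 2.18). None of 31 S phase and replication genes reached 2-fold, but 2 alone had ratios above 1 (median -0.30, 0.12th percentile); Pcna was at 0.810-fold and the helicase gene Mcm6 at 0.715-fold. The 29 mitotic genes showed no such shift (median -0.01, 71.7th percentile), with Top2a at 1.06-fold and Mki67 at 0.981-fold. The 41 cytosolic ribosomal protein genes had 5 ratios above 1 and none at 2-fold (median -0.24, 0.03rd percentile), with Rplp0 at 0.724-fold and Rps2 at 0.964-fold.

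Immune genes differed in both directions. Of 22 measured cytokine and chemokine genes, 7 were higher and 2 lower, and their median of 0.65 was above the random lists, with an order-statistic interval of -0.43 to 1.11. Ccl2 was 4.21-fold higher (2.86 to 6.35, from 33 counts), Vegfa is described above, and Cxcl2 was 3.56-fold higher (2.196 to 5.999). Cx3cl1, the ligand of the microglial receptor CX3CR1, was 2.52-fold lower (2.27 to 2.81), and Cxcl5 2.12-fold lower (log2 ratio -1.08, or -0.995 with a pseudocount of 5). Of 18 NF-kB targets, which include Ccl2 and Cxcl2, 4 were higher and 1 lower (median 0.07, 83.1st percentile); Vcam1 was 2.68-fold higher, while the inhibitor gene Nfkbie was 8.41-fold lower (5.33 to 13.9). Of 26 type I interferon genes 4 were higher and 1 lower (median 0.18, 98.1st percentile, order-statistic interval -0.25 to 0.40). Mx1, an antiviral GTPase, was 6.60-fold higher (5.40 to 8.13). Rsad2 was 4.90-fold higher (2.84 to 8.98, from 16 counts) and Isg15 4.35-fold (2.35 to 8.66, from 13 counts). Ifi27l2a was 2.07-fold lower, though under 2-fold with upper quartile scaling (log2 ratio -0.99) or the trend removed (-0.95). Without a minimum count this list lay at the 96.8th percentile, and with the trend removed at the 95.3rd. Among 25 antigen presentation and checkpoint genes, 2 were higher and 1 lower (median -0.13 and mean 0.06, of opposite sign; 20.1st percentile). Nt5e, the adenosine-producing ectoenzyme CD73, was 6.44-fold higher (4.01 to 10.9), Cd274, which encodes PD-L1, 3.20-fold (2.51 to 4.11), and the immunoproteasome gene Psmb9 2.43-fold lower.

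Receptor tyrosine kinase and lipid synthesis genes included members lower in the knockout library. Of 16 measured genes of the receptor tyrosine kinase list, 3 were lower, none was higher and 6 had ratios above 1. Their median of -0.49 lay at the 0.02nd percentile, with an order-statistic interval of -0.82 to 0.20. Epha4, an ephrin receptor tyrosine kinase gene with 0 counts in WT and 48 in the knockout, was not on this list. Mertk was 2.33-fold lower (1.88 to 2.91), Erbb2 2.29-fold (2.02 to 2.60) and Ephb4 2.18-fold (2.05 to 2.32), the last at a log2 ratio of -0.94 with the trend removed. Of 24 MAPK feedback and immediate early genes, 3 were higher (Epha4, the phosphatase gene Dusp1 at 2.48-fold and the AP-1 gene Fosl1 at 2.55-fold) and Spry1 was 2.10-fold lower (log2 ratio -1.07, or -0.96 with the trend removed); the median of 0.14 lay at the 96.6th percentile. Of 14 fatty acid synthesis genes, the desaturase gene Fads2 was 2.02-fold lower (1.92 to 2.13) and 4 had ratios above 1 (median -0.32, 0.59th percentile, order-statistic interval -0.47 to 0.45). Fads2 was under 2-fold with total count scaling (log2 ratio -0.99), upper quartile scaling (-0.95) or the trend removed (-0.93), and with the trend removed the list lay at the 3.12th percentile. Of 25 cholesterol genes, Nsdhl was 2.22-fold lower (median -0.16, 10.3rd percentile). Nuclear-encoded respiratory chain genes (30 measured) had none at 2-fold and a median of 0.12 (98.7th percentile, or 96.8th with the trend removed; order-statistic interval -0.14 to 0.18), with Atp5b at 1.13-fold and Atp5a1 at 0.914-fold. None of 26 lysosome and autophagy genes reached 2-fold (median 0.07, 94.4th percentile), with Lamp1 at 1.45-fold and Ctsz at 1.27-fold.

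Matrix, adhesion and lineage genes went both ways. Of 26 matrix genes 3 were higher and 2 lower (median -0.02 and mean 0.10, of opposite sign; 53.2nd percentile). The collagenase gene Mmp13 was 5.43-fold higher (3.31 to 9.37), Tnc 2.73-fold from 16 counts and Loxl2 2.36-fold (2.12 to 2.63), while Col6a1 was 2.71-fold and Thbs1 2.41-fold lower (2.316 to 2.501). Of 26 genes of the mesenchymal list 2 were higher, the epithelial adhesion gene Epcam at 2.76-fold and Fosl1, and 3 were lower (median 0.07 and mean -0.05, of opposite sign; 87.6th percentile). The lower ones were Tgfbi (4.02-fold, 3.12 to 5.24), S100a4 (21 counts against 2; WT over knockout ratio 10.6, 2.59 to 93.2) and Runx1 (18 against 7; log2 ratio -1.38, or -0.95 with a pseudocount of 5). The mesenchymal list also holds the epithelial genes Epcam and Cdh1, so its counts and median have no single direction. Of 18 YAP-TEAD targets, Ctgf was 2.17-fold and Ankrd1 2.03-fold higher (median -0.10, 30.4th percentile). Only 12 of 32 glial and neural lineage genes were measured; Id2 was 2.38-fold and the glutamate transporter gene Slc1a2 2.16-fold lower (log2 ratio -1.11 for Slc1a2, or -0.99 with a pseudocount of 5), and the list median was -0.02 (56.2nd percentile).

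**Figure D3:**
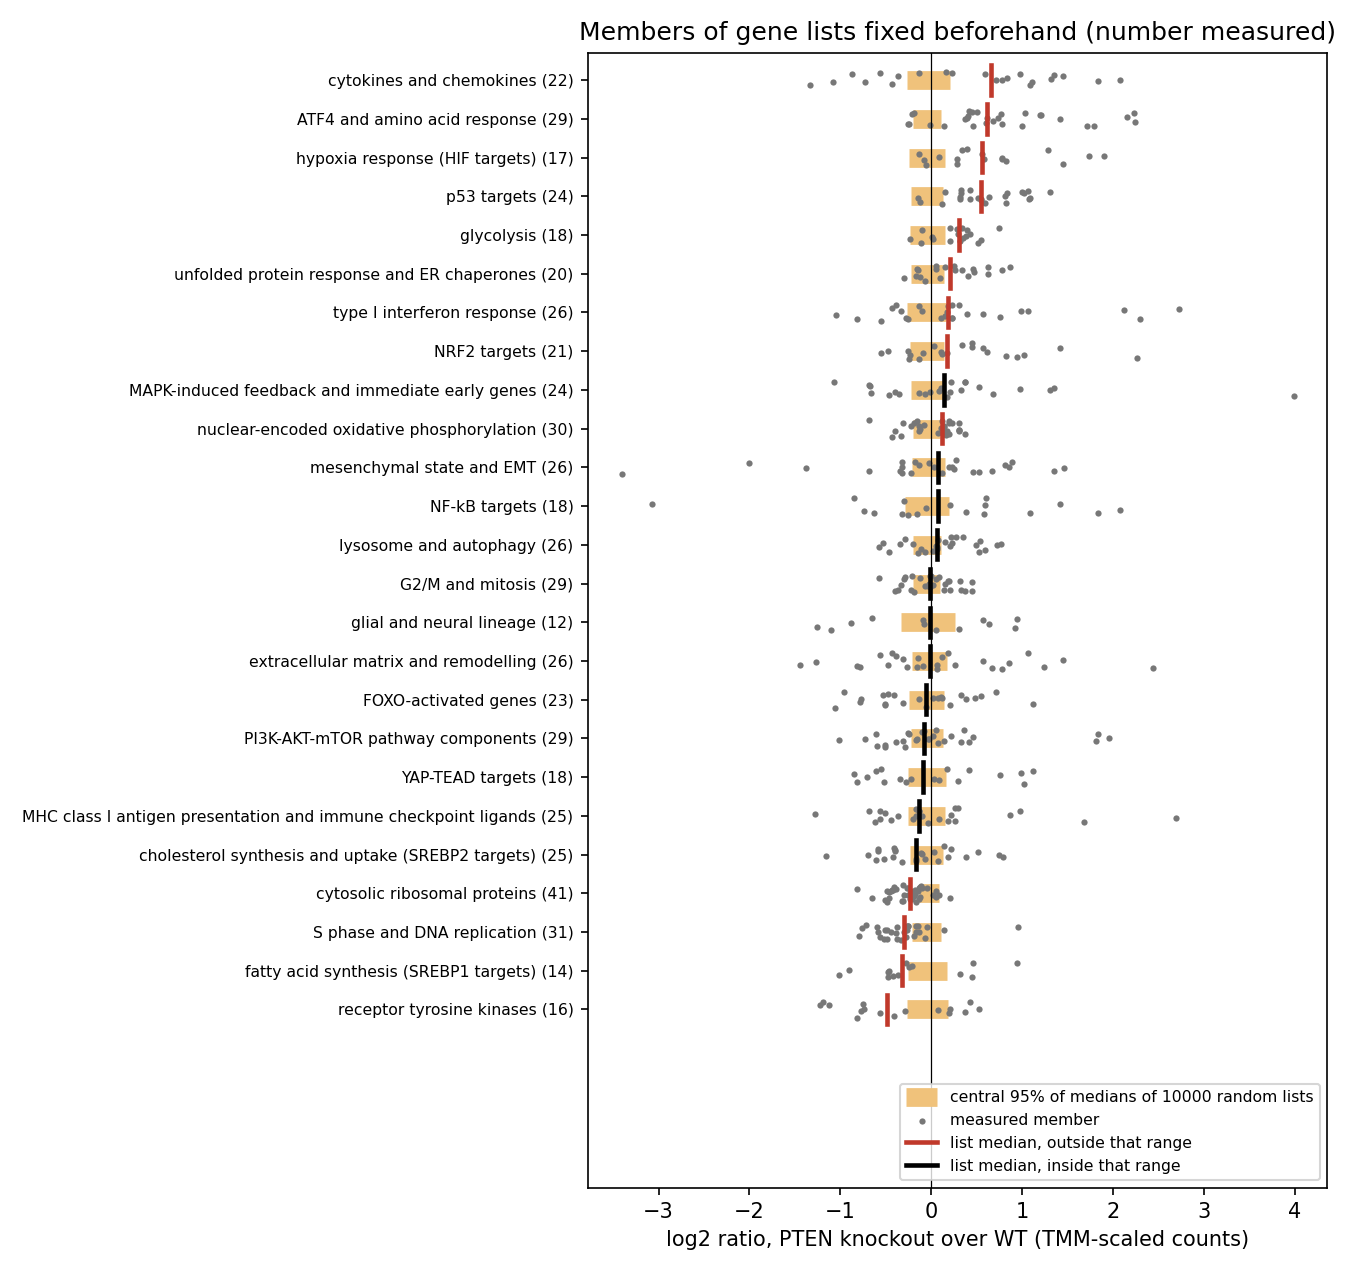
Log2 ratios of the measured members (grey points) of 25 gene lists, with each list's median (vertical line) and the central 95% of the medians of 10000 matched random lists (orange). Medians of the ATF4, HIF, p53 and cytokine lists lie between 0.55 and 0.65, to the right of the orange ranges, and the receptor tyrosine kinase median lies at -0.49, to the left.

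Markers of other cell types and of RNA quality were read as controls. Of 19 macrophage and microglia markers 3 were measured: Cd68 was 2.83-fold higher, Csf1r 3.14-fold lower and Cd14 at 1.13-fold. Lymphocyte markers were limited to Trac (43 and 24 counts), neuronal ones to Map2 (23 and 6) and Syn1 (12 and 16), and red cell ones to Alas2 (13 and 12) and Hba-a1 (7 and 14). Endothelial markers (4 measured, 83.8th percentile) included Esam at 1.33-fold, Vwf at 1.22-fold, Pecam1 at 1.53-fold and Kcnj8 at 0.942-fold. Fibroblast markers (7 measured, 1 higher, 52.0th percentile) included Gsn at 1.00-fold, Dcn at 0.742-fold, Pdgfra at 1.35-fold and Col1a1 at 0.582-fold. Epithelial keratins were abundant in both libraries: Krt8 had 21952 and 24549 counts, Krt18 14512 and 14565, Krt19 7106 and 15764 (2.199-fold higher), and the claudin gene Cldn3 6112 and 4779 (9 measured, 2 higher and none lower, 69.9th percentile). Mitochondrial transcripts had a median of -0.24 (4th percentile) and 1 of 15 lower, with mt-Co1 at 1.04-fold, mt-Cytb at 0.821-fold, mt-Nd1 at 0.836-fold and mt-Nd5 at 1.11-fold. Of 7 measured histone genes, 1 of them higher (median 0.48, 96.4th percentile) H1f0 was at 1.39-fold, H2afz at 0.974-fold, Hist1h1c at a log2 ratio of 0.58 and Hist1h2bc at 2.56-fold. Nuclear and structural RNAs (6 measured, 74.2nd percentile) included Malat1 at 1.58-fold, Neat1 at 1.69-fold, Gas5 at 0.937-fold and Snhg1 at 0.802-fold.

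In all, 9 of the 32 lists with enough measured members had medians above the central 95% of random lists and 4 below. Unrelated genes would put about 1.6 lists outside these limits. The order-statistic interval of the median excluded 0 for 6 of these 13 lists (ATF4, HIF, glycolysis, p53, S phase and ribosomal protein genes) and included 0 for the other 7. That interval treats the members of a list as independent.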

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

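The counts of genes depended on the fold threshold and the minimum count more than on scaling. At a summed count of at least 100, 342 genes were higher and 301 lower; at 4-fold, 287 and 117; at 1.5-fold, 1568 and 1560. With the interval bound itself beyond 2-fold they were 377 and 201. Without Gm, Rik and similar names 600 genes were higher and 424 lower, against 925 and 624 with them. Under total count, DESeq2 and upper quartile scaling the higher genes numbered 977, 953 and 1040 and the lower ones 573, 602 and 529, and the median log2 ratio of all genes stayed between -0.02 and 0.03. The log2 ratio of Pten stayed between -0.62 and -0.56 in the 6 alternatives that apply to it. Between 12 and 16 lists lay outside the limits of random lists in the 9 alternatives tried for them. Total count, DESeq2 and upper quartile scaling shift every log2 ratio equally, so they could not change a list's percentile. Thinning took the WT library only from 15435592 to 15259259 counts. No list outside the limits changed sign under the 9 alternatives. In the 6 alternatives that give single genes another value, no called gene named in the report changed sign, and 9 came under 2-fold in at least 1, all of them lower ones, as given in the report. At the minimum of 100, 21 of the called genes named are not measured, Muc5ac, Hnf4a, Epha4 and Rgl3 among them. With the GC and length trend removed the fatty acid, interferon and respiratory chain lists came inside the limits, while the MAPK (97.7th percentile), lysosome (99.7th) and mitochondrial (0.23rd) lists came outside. With the deeper library thinned the MAPK (98.1st) and histone (97.7th) lists were outside, and at a summed count of 100 the NF-kB (98.3rd), glial (98.7th) and histone (97.9th) lists. The median changed sign in at least 1 alternative for 8 lists inside the limits (PI3K, FOXO, mitotic, matrix, glial, fibroblast, mitochondrial and nuclear RNA), and Mki67, Krt18, Rps2, H2afz and mt-Co1, all near equal levels, changed side. The causes were not tested. No paired analysis was possible because each genotype has 1 library, and no replicate could be left out. Depth limits genes with few counts: the floor of 3 counts is 0.196 CPM in WT and 0.195 CPM in the knockout.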

Other observations

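The further Wnt target and EGFR ligand lists were written after the values in the report had been seen but before those lists were tested, and Lgr5, Wnt10a, Trp53, H2-K1, H2-D1, Krt7, Krt20 and Vil1 were picked after their values were seen. Wnt-related genes beyond those of the report were also lower in the knockout library. Lgr5, a stem cell receptor and Wnt target, went from 3355 to 1175 counts (log2 ratio -1.53), and Wnt10a, which lies beside Wnt6 on chromosome 1, from 141 to 19 (-2.90). A hypothesis of lower Wnt pathway output was tested on a list of other Wnt targets. Of 12 measured, 3 were at least 2-fold lower, none was higher and 10 had ratios below 1; the log2 ratio was -1.25 for Nkd1, -1.11 for Sp5, -1.63 for Tnfrsf19 and -0.71 for Axin2. Their median of -0.45 lay at the 0.11th percentile of random lists, which is consistent with the hypothesis in these 2 libraries; a difference between cultures that has nothing to do with the edit remains open.

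None of the other measured EGFR ligand genes rose as Areg and Btc did. Besides these, 3 genes of that list were measured and 0 of them were at least 2-fold higher (0%). The log2 ratio was -0.08 for Tgfa, 0.37 for Hbegf and -0.25 for Egf, the last from 26 and 22 counts. So few genes do not settle whether the class moved. Trp53 was lower (2384 counts against 1302, log2 ratio -0.89) while its targets were higher as a group. H2-K1, a classical MHC class I gene, had 0 counts in both libraries, whereas H2-D1 had 10266 and 11803. How reads of similar gene copies were counted is not given, so 0 counts need not mean that H2-K1 was not expressed.

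Both libraries were rich in epithelial and poor in glial transcripts, which stands out for a line labelled glioma. Krt8, Krt18 and Krt19 are given in the report; Krt7 had 10730 and 11031 counts, Krt20 5655 and 5166, and Vil1, an actin bundler of the brush border, 1237 and 3227. Of 32 glial and neural genes, 20 had fewer than 20 summed counts and 7, among them Sox2, Olig2 and Aqp4, had 0 in both libraries; Gfap had 1 and 3 counts. The log2 ratio was 0.15 for Krt8, -0.01 for Krt18, 0.03 for Krt7 and -0.14 for Krt20, against 1.14 for Krt19 and -0.37 for Cldn3. An epithelial programme in the cultured cells, an admixture of other cells, and cells other than the labelled line stay open as untested, since no independent profile of this line was used here. If the cells were not the labelled line, every ratio in the report would describe that other line.

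Neighbouring genes shifted together along some chromosomes. Of 20 chromosomes, 14 had medians outside the central 95% of random draws before the GC and length trend was removed. The median log2 ratio was 0.19 for chromosome 1, 0.10 for chromosome 9, -0.24 for chromosome 12 and -0.23 for chromosome 19. With the trend removed these were 0.22, 0.14, -0.23 and -0.16. Medians of chromosomes 4, 5 and 7 shrank from -0.079, -0.077 and -0.075 to -0.015, -0.018 and -0.0046. Those of chromosomes 10 and 15 grew from 0.05 and 0.04 to 0.12 and 0.11. In blocks of 100 neighbouring measured genes, 9 of 130 lay above and 9 below all 10000 random draws; the highest, near the end of chromosome X (129749742 to 170019281), which holds 124 genes, was at 0.35, and the lowest, on chromosome 19 (6046576 to 10882001), at -0.38. After removal of the GC and length trend 7 of the 9 high and 6 of the 9 low blocks remained beyond the random draws, so that trend is not the whole cause. In blocks picked by their odd-numbered genes, the even-numbered genes lay on the same side in 31 of 31 (100%), consistent with an effect that follows position, for which a copy number difference between the 2 cell populations is a candidate explanation and shared regulation of domains another.

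The genes around Pten did not settle whether its lower transcript was a regional effect. The 40 measured genes nearest to Pten (chromosome 19, 28963953 to 36621135) had a median log2 ratio of -0.029 (95% order-statistic interval -0.30 to 0.32), above the counting interval of Pten (-0.68 to -0.55). That had been set as evidence against a lower dosage of the region, but the bound left out how far single genes vary: their SD was 1.14, more than the distance to Pten, 21 of the 40 lay below 0 and 6 below Pten. The block of 100 genes that holds Pten (10895231 to 36621135) was at -0.19, or -0.16 with the GC and length trend removed. It did not lie beyond the random draws either way. Chromosome 19 was at -0.23, or -0.16 with that trend removed. A regional contribution was neither shown nor excluded. With the GC and length trend removed Pten was at -0.62, so that trend does not account for it; loss of part of the transcript in edited cells and variation between cultures were not tested.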
